A study of Homo sapiens with 17 samples.

How the data were processed

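RNA was sequenced from C4-2 cells, a castration-resistant human prostate cancer line, in 17 samples, each of which the labels place in 1 group. The CAMKK2 table held 3 Cas9 control samples and 3 CAMKK2 knockout samples. The CREB table held 1 Cas9 sample, 2 samples each labelled as CREB1 knockout, ATF1 knockout and double knockout, and 1 sample each of cells labelled CREB1 knockout with wild-type CREB or CREB S133A added back. The treatment table held 1 sample with vehicle (DMSO) and 1 with 500 nM of a small-molecule CREB inhibitor, both after 72 h. Per the labels' protocols, total RNA with an integrity number above 8 was depleted of ribosomal RNA, and libraries were made from 500 ng of it with 8 PCR cycles and read as paired ends of 76 nt. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.0f, HTSeq 0.11.0, DESeq2 1.30.1 and the GRCh38 build, without saying which step made which table.

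The deposited values are whole-number counts per gene, not normalized, for the same 39109 Ensembl genes in each table. In the CREB and treatment tables each sample had 3 technical columns. Those columns differed from each other by a chi-square per gene of 1.17 to 1.28, against 150 to 291 between samples of 1 group in the CREB table, so they were summed and each sample counted as 1 replicate. No column of another sample was left unused. Totals ran from 13077825 to 45101670 counts in the CAMKK2 table and from 34229907 to 77210078 in the CREB table, and were 70445411 with DMSO and 46225445 with the inhibitor. Of the gene identifiers, 39085 (99.9%) were found in the GENCODE 29 annotation, which gave coordinates, chromosomes, GC share and length.

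Counts were tested in R 4.3.3 with edgeR 4.0.16: trimmed-mean (TMM) scaling, its filter for low counts, a robust quasi-likelihood fit with 1 coefficient per group, and Benjamini-Hochberg adjustment, with genes called at an adjusted p under 0.05. The CAMKK2 table was fitted alone (14546 genes). The CREB table was fitted as a whole (22216 genes), because its Cas9 and addback groups hold 1 sample each and were assumed to vary like the paired knockout samples. The labels do not say that samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. CPM values are TMM-scaled and given with the SD, and log2 fold changes with the SE of the fit. The inhibitor and DMSO had 1 sample each and no test: log2 ratios of CPM used a prior count of 2 over 13506 genes with at least 200 counts in the pair, and a list's median was placed among 10000 random lists matched on expression. Intervals given there cover counting error only.

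Gene lists (27 lists, 529 genes) were fixed before the data were examined, as were the designs and the rule for named genes, and the other settings listed below. The lists cover cholesterol and lipid genes, CREB and its targets, calcium and AMPK kinases, androgen receptor genes, cell cycle, stress, interferon and energy genes, markers of other cell types, and signs of RNA quality. Of the listed symbols 3 were not found. The lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes are the 3 targets, the 6 genes of lowest p called in each direction with a mean log2 CPM of at least 2 and a proper symbol, and per list the 2 members of lowest p called each way, or otherwise the 2 of highest expression as values. For the inhibitor they are the 6 highest and 6 lowest log2 ratios and the 2 highest and lowest of each list. A gene named outside this rule is said to be so.

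Set before the data were examined and tried in turn were other scaling, other filters, DESeq2 1.42.0, limma voom, stricter thresholds, each sample left out in turn, and a block for shared sample numbers. On simulated counts with 200 changed genes, the CAMKK2 design recovered 39.4% of genes changed 2-fold, 96.9% at 4-fold and 100% at 8-fold. The design for CREB1 knockout against Cas9 recovered 4.55%, 31.8% and 50% at the same sizes, that for double against CREB1 knockout 16.4%, 53.7% and 83.3%, and that for wild-type against S133A addback 2.99%, 21.2% and 47%. False calls were 12 of 166 for the CAMKK2 design and 18 of 75, 22 of 124 and 13 of 60 for the other 3, above the 5% aimed at. In those 3 designs 4.83%, 4.78% and 5.2% of unchanged simulated genes had an unadjusted p under 0.05. In the CREB table itself only 421, 348 and 43 of all 22216 genes did, where 1111 would by chance. The recovery rates may therefore be too high for that table. In the CAMKK2 simulation noise was independent between samples, so the shared difference of Cas9 2 and CAMKK2 KO 3 described below was missing. A block for that difference left 2-fold recovery at 37.9% there, while in the data it took the calls from 361 to 4762. The rates of the CAMKK2 design may therefore not hold for the real samples.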

Results

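The study asked how the kinase CAMKK2 acts through the transcription factor CREB in castration-resistant prostate cancer cells, and whether cholesterol metabolism is part of that route. RNA was counted in C4-2 cells that lacked CAMKK2 (3 samples against 3 Cas9 controls), in cells labelled as lacking CREB1, its relative ATF1 or both (2 samples each against 1 Cas9 control), in cells labelled CREB1 knockout with wild-type CREB or the S133A mutant added back (1 sample each), and in cells given a CREB inhibitor or vehicle (1 sample each). Totals per sample ran from 13077825 to 77210078 counts.

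The targeted genes were measured first. CAMKK2 (ENSG00000110931; chromosome 12, 121237691 to 121298308, GRCh38) fell from 150 ± 27.5 CPM in Cas9 cells to 17.1 ± 2.79 CPM in the knockout (SD, n = 3 each), a log2 fold change of -3.14 (SE 0.21, edgeR adjusted p = 0.0020). CREB1 (ENSG00000118260; chromosome 2, 207529737 to 207603431) stood at 68.2 CPM in the Cas9 sample of the CREB table, 108 ± 54 CPM in the samples labelled CREB1 knockout and 134 ± 11.6 CPM in those labelled double knockout (n = 2 each), so its mRNA was not lower in them. It reached 491 CPM with wild-type CREB added back and 402 CPM with S133A, the mutant that lacks the serine phosphorylated when CREB is activated. ATF1 (ENSG00000123268; chromosome 12, 50763710 to 50821122) stood at 27.1 CPM in Cas9 cells, 33.9 ± 6.11 CPM in the samples labelled ATF1 knockout and 32.7 ± 4.13 CPM in those labelled double knockout. A disrupted reading frame need not lower an mRNA, so these levels check the CAMKK2 labels but not the CREB1 and ATF1 labels.

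**Figure D1:**
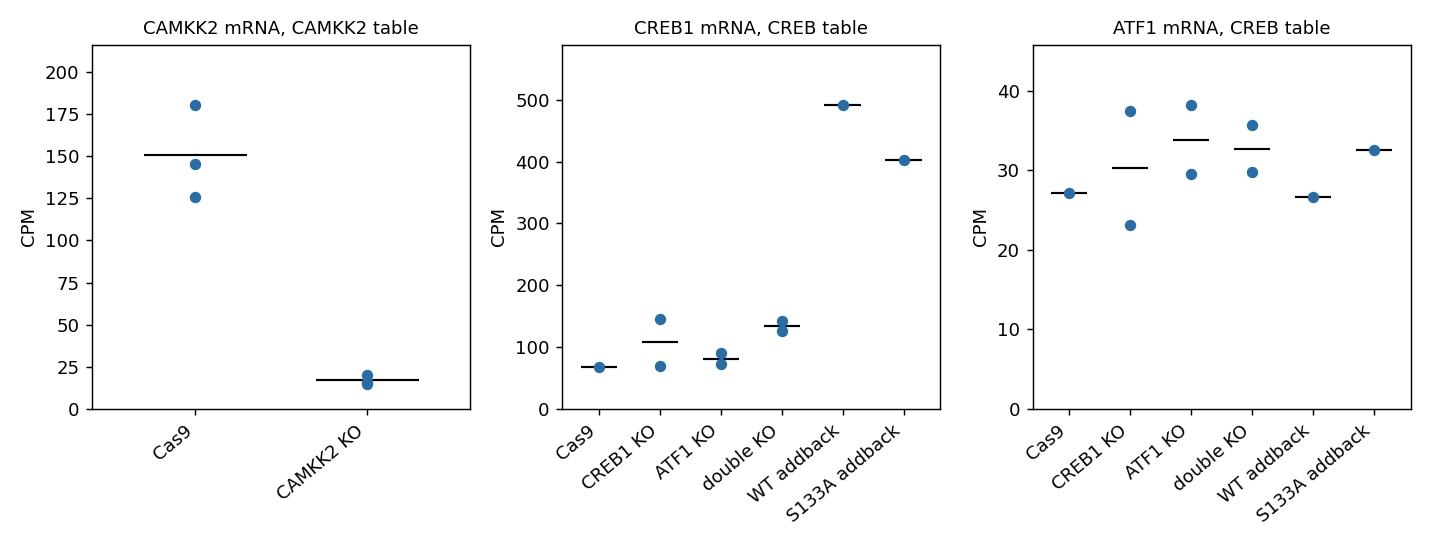
CAMKK2, CREB1 and ATF1 mRNA in CPM per sample (points) with the group mean (line), CAMKK2 in the CAMKK2 table and the other genes in the CREB table. CAMKK2 was lower in all 3 knockout samples, while CREB1 was 68.2 CPM in Cas9 cells and 491 and 402 CPM in the addback samples.

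In CAMKK2 knockout samples SLC22A3, an organic cation transporter, rose from 7.31 ± 0.358 to 138 ± 4.76 CPM (log2 fold change 4.24, SE 0.14, edgeR adjusted p = 0.000146). The pseudokinase gene TRIB2 rose from 17.3 ± 1.58 to 291 ± 20.1 CPM, and DDC, the aromatic amino acid decarboxylase that also binds the androgen receptor, from 26.2 ± 1.74 to 207 ± 16.4 CPM (log2 fold changes 4.07, SE 0.15, and 2.98, SE 0.14). The protocadherin gene PCDH7 (3.34, SE 0.19), the secreted synapse organizer CBLN2 (2.43, SE 0.14) and the insulin receptor adaptor GRB10 (1.88, SE 0.14) also rose. Among genes that fell, AGR2, a disulfide isomerase of secretory epithelia, went from 37.4 ± 4.7 to 4.33 ± 0.392 CPM (log2 fold change -3.11, SE 0.17) and the actin-binding TMSB4X from 32.8 ± 6.17 to 3.28 ± 0.0339 CPM (-3.32, SE 0.19). The transcription factor PAX1 (-2.27, SE 0.13), the cyclooxygenase PTGS1 (-2.40, SE 0.16) and the phospholipase PLD1 (-2.33, SE 0.19) fell as well. In all, 156 genes were called higher and 205 lower of 14546 tested with edgeR.

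Genes of cholesterol biosynthesis did not move together in CAMKK2 knockout cells: 0 of 21 passed edgeR's test, over all genes and adjusted over the list alone, and their median log2 fold change was 0.05 (camera adjusted p = 0.889). Among the most abundant members, the squalene synthase FDFT1 stood at -0.34 (SE 0.12, adjusted p = 0.221, unadjusted p = 0.0207). Among all genes tested, 2088 had an unadjusted p under 0.05, and for these 21 genes a fit that set the samples Cas9 2 and CAMKK2 KO 3 apart from the other 4 as a block, added after the data were seen, called 5 higher, among them CYP51A1, PMVK, FDPS and TM7SF2, and 1 lower, FDFT1. Of the sterol sensing and uptake genes 1 of 16 rose, LPIN1, which makes diacylglycerol and is itself controlled by sterol-regulated factors (1.06, SE 0.14). Of the sterol efflux and esterification genes 1 of 10 fell, the cholesterol exporter ABCA1 (-1.77, SE 0.21, 7.06 ± 1.48 to 2.09 ± 0.0986 CPM). None of 20 fatty acid synthesis genes was called with edgeR, and FASN and FADS2, the most abundant, stood at 0.15 (SE 0.29) and 0.18 (SE 0.10). With the block, 6 were higher and 1 lower, among them the acyl-CoA synthetases ACSL3 (0.75, SE 0.06) and ACSL4 (0.77, SE 0.10) and, lower, HACD3 (-0.19, SE 0.06). The block also called 4 sterol sensing and uptake genes higher and 4 lower, and 2 efflux and esterification genes higher and 3 lower. Such counts stand beside 2513 genes higher and 2249 lower of all 14546 in that fit.

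Among CREB target genes the orphan receptor gene NR4A2 fell in CAMKK2 knockout samples (-1.31, SE 0.22, edgeR adjusted p = 0.0354), 1 of 18 members, while the list's median was 0.01, and adjusted over the list alone 2 members were lower. With Cas9 2 and CAMKK2 KO 3 as a block, 2 members were higher, CITED2 (0.59, SE 0.06) and PER2 (0.65, SE 0.09), and 4 lower, among them NR4A2 and the G protein regulator RGS2 (-0.83, SE 0.15). None of the 17 CREB family and coactivator genes passed (1 higher with the block), and of 18 calcium and AMPK kinases CAMKK2 alone was called, with 2 lower adjusted over the list alone. With the block, CALM2 (0.42, SE 0.06) and STK11 (0.26, SE 0.06) were higher and 4 lower, among them CAMKK2 and CAMK2B (-1.85, SE 0.12). The list, which includes CAMKK2 itself, had a camera adjusted p of 0.0628, and with chromosome 2 left out of 0.0352 (lower; adjusted p = 0.857 with an estimated correlation). Among androgen receptor targets the transporter SLC45A3 (1.02, SE 0.15) and the cold channel TRPM8 (0.83, SE 0.16) rose, 2 of 33, with a list median of 0.17 and a camera adjusted p of 0.0958. With the block, 15 were higher and 3 lower and the list passed camera (adjusted p = 0.0233; adjusted p = 0.653 with an estimated correlation), also with chromosome 2 left out (13 higher, 3 lower, adjusted p = 0.0352; adjusted p = 0.857 with an estimated correlation). The lactate exporter SLC16A3 of the glycolysis and hypoxia list (1.27, SE 0.21) and the intermediate filament VIM of the mesenchymal list (0.99, SE 0.15) rose. The interferon response list had a median of 0.48 over 19 genes and was the 1 list that passed camera with the preset correlation (adjusted p = 0.0275; adjusted p = 0.632 with an estimated correlation), which it did not with the block (adjusted p = 0.0628; 10 higher, 3 lower). In it IFIT2 rose (1.35, SE 0.24) at a low level of 0.762 ± 0.119 to 2.01 ± 0.367 CPM, and adjusted over the list alone 6 genes were higher. The calls of LPIN1, ABCA1, NR4A2, SLC45A3, TRPM8, IFIT2, SLC16A3 and VIM were lost without Cas9 3, while their directions stayed. No member of the G1/S (median 0.09), G2/M (0.14), p53 (0.09), unfolded protein and ATF4 (0.03), nuclear oxidative phosphorylation (0.06), autophagy (-0.02) or ribosomal protein (-0.02) lists was called without the block. With it, the genes called higher and lower numbered 6 and 0 for G1/S, 10 and 0 for G2/M, 7 and 3 for p53, 6 and 3 for unfolded protein and ATF4, 7 and 0 for oxidative phosphorylation, 2 and 8 for autophagy and 1 and 2 for ribosomal proteins, and none of these lists passed camera. The genes named from the block alone were chosen after their values were seen. Of all 14546 genes the block called 2513 higher and 2249 lower, so called members alone do not set a list apart.

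The samples Cas9 2 and CAMKK2 KO 3 stood apart from the other 4 on the first principal component (49.8% of variance), and genotype followed on the second (37.6%). With these 2 kinds of sample as a block, added after the data were seen, edgeR called 2513 genes higher and 2249 lower. Among them were all 361 genes called without the block, in the same direction. That is not separate support, since the block was read from these same samples and mainly lowers the error. CAMKK2, for example, went from -3.14 (SE 0.21) to -3.15 (SE 0.08). The SEs and calls of the blocked fit may therefore be too favourable. Without the block, leaving out Cas9 3 brought the count to 24. Genes of chromosome 2 were higher as a whole in all 3 knockout samples, with a median log2 fold change of 0.35 over 846 protein-coding genes in the blocked fit, and 32 (21.2%) of the protein-coding genes called higher lay there against 6.51% of those tested. Chromosomes 6 and 16 had medians of -0.15 and -0.13 in the blocked fit, and 18 (9.28%) and 29 (14.9%) of the protein-coding genes called lower lay there, against 5.06% and 4.57% of those tested. TRIB2, LPIN1, TRPM8, ACSL3, PER2, CALM2 and, though lower, NR4A2 are on chromosome 2, as are 3 of the interferon list, including IFIH1. CALM2 at 0.42 is near that chromosome's median. With its genes left out, the interferon list had a median of 0.22 over 16 genes and a camera adjusted p of 0.172.

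**Figure D2:**
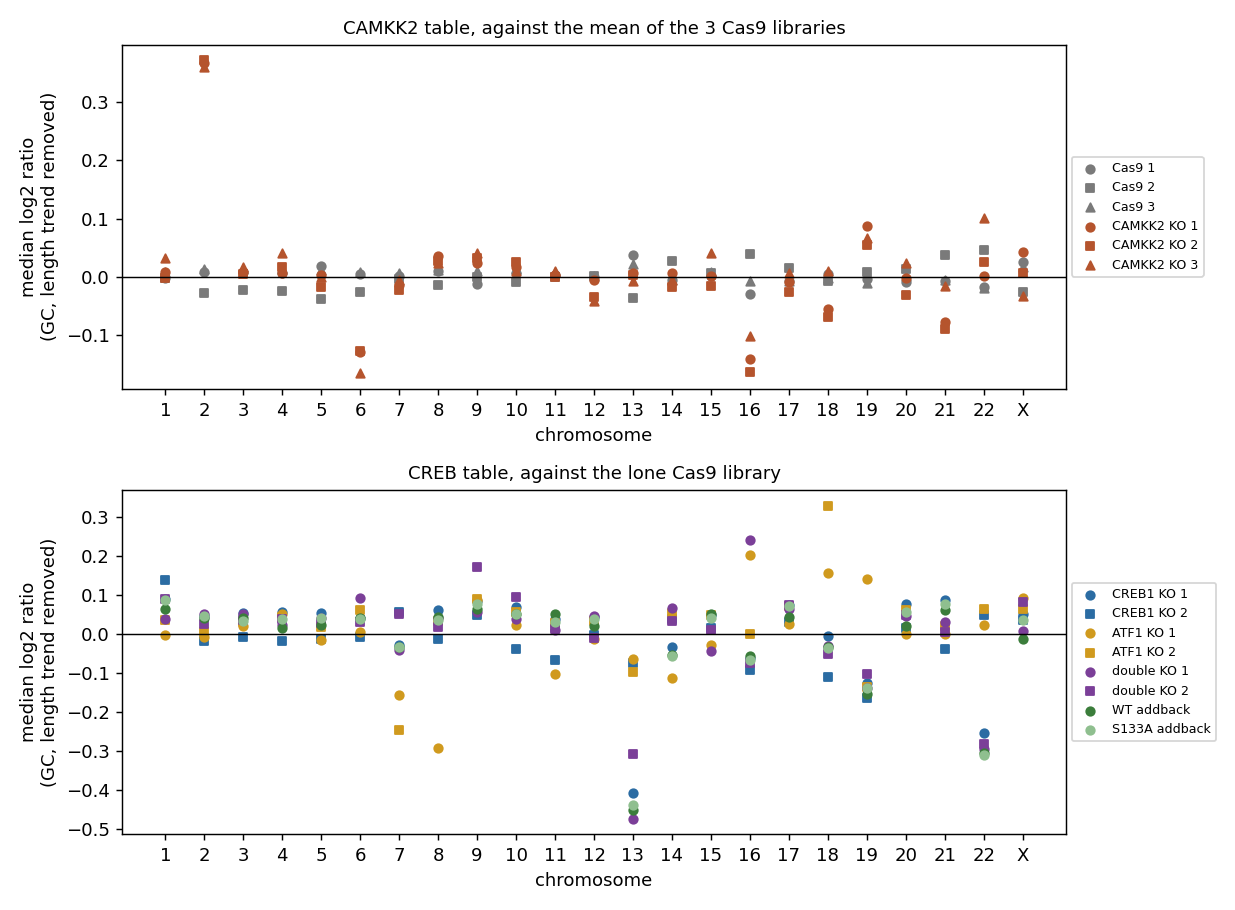
Median log2 ratio of expressed protein-coding genes per chromosome, with the trend on GC share and length taken out, for each sample of the CAMKK2 table against the mean of the Cas9 samples (top) and of the CREB table against its Cas9 sample (bottom). Chromosome 2 stood at 0.37, 0.37 and 0.36 in the 3 CAMKK2 knockout samples, and chromosome 13 at -0.41 in CREB1 KO 1 and -0.47 in double KO 1.

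Samples labelled CREB1 knockout, ATF1 knockout or double knockout were set against the lone Cas9 sample to ask which genes need these factors. BMPR1B, a bone morphogenetic protein receptor, had 19.4 CPM in Cas9 cells, 79.7 and 90.7 CPM in the samples labelled CREB1 knockout, 71.8 and 55.9 CPM in those labelled ATF1 knockout and 110 and 125 CPM in those labelled double knockout, and 38.4 and 40 CPM in the wild-type and S133A addback samples. The mucin gene MUC5AC had 10.6 CPM in Cas9 cells against 1.37 and 0.869 CPM with the double knockout label, and the Wnt ligand WNT5A 146 CPM against 53.2 and 40.4 CPM, while the samples labelled CREB1 knockout had 137 and 167 CPM of WNT5A. The matrix metalloproteinase MMP16 had 272 CPM in Cas9 cells and between 3.10 and 48.2 CPM in all 6 samples labelled as knockouts, and 75.2 and 73.7 CPM in the addback samples, so that the lone Cas9 sample stood above the other 8. These 4 genes were chosen after their values were seen, since no gene passed the test: edgeR called 0 genes in each of the 3 comparisons, where 421, 269 and 978 genes had an unadjusted p under 0.05 and 1111 would by chance. DESeq2 called 3, 6 and 30 genes, and voom 0 in each.

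Cholesterol biosynthesis genes had median log2 fold changes of 0.11, 0.11 and 0.25 with the CREB1, ATF1 and double knockout labels, and 0 of 21 passed edgeR (camera adjusted p = 0.371, 0.744 and 0.130). The samples of a label differed: the list's median against Cas9 was 0.37 and -0.06 for CREB1, 0.22 and -0.24 for ATF1, and 0.54 and -0.04 for the double knockout. The lamin B receptor LBR, a sterol reductase, stood at -0.80 (SE 0.36, unadjusted p = 0.0460) with the double knockout label. CREB target genes had medians of 0.16, 0.22 and 0.31, and did not pass camera (adjusted p = 0.368, 0.0892 and 0.118). In the single samples against Cas9 they had 0.12 and -0.16, 0.09 and 0.19, and 0.10 and 0.42. Androgen receptor targets had medians of 0.39, 0.23 and 0.58 and passed camera with the preset correlation (adjusted p = 0.0021, 0.0024 and 2.59e-05), as did ribosomal proteins at 0.44, 0.24 and 0.42 (6.09e-06, 0.000509 and 0.000154), though the 2 samples labelled ATF1 knockout had ribosomal medians of 0.03 and 0.50 against Cas9. With an estimated correlation the adjusted p was 0.497, 0.438 and 0.332 for androgen receptor targets and 0.522, 0.684 and 0.687 for ribosomal proteins. The p53 targets had a median of 0.57 with the double knockout label (19 of 20 genes positive, adjusted p = 2.59e-05 preset and 0.359 with an estimated correlation). The interferon list had 0.39 with the CREB1 label (adjusted p = 0.0133 preset and 0.497 with an estimated correlation), but 0.63 and 0.02 in its 2 samples.

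Knockout labels were also compared with each other. Against the samples labelled CREB1 knockout, those labelled double knockout had a WNT5A log2 fold change of -1.70 (SE 0.30, unadjusted p = 0.000172) and p53 targets had a median of 0.36 (camera adjusted p = 1.26e-07 preset, 0.426 with an estimated correlation). Against those labelled ATF1 knockout, the cell adhesion gene NFASC stood at 2.87 (SE 0.45) and MUC5AC at -3.78 (SE 0.47). Between the labels CREB1 and ATF1 knockout, the chaperone gene CLU stood at 1.48 (SE 0.31) and the kinase gene GASK1B at -2.68 (SE 0.43). These genes too were chosen after their values were seen, and edgeR called 0 genes in the 3 comparisons, with 348, 1128 and 782 at an unadjusted p under 0.05, while DESeq2 called 1, 104 and 45 and voom 0. For the test of whether the double knockout differs from the sum of the single ones, edgeR, DESeq2 and voom called 0 genes, with 167 at an unadjusted p under 0.05 in edgeR. In it ID3, an inhibitor of helix-loop-helix factors, stood at 3.14 (SE 0.96), again chosen after its value was seen. The lone Cas9 sample enters that test, so a gene high in that sample alone also comes out positive.

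Adding CREB back to cells labelled CREB1 knockout asked which changes depend on CREB and on the serine that S133A lacks. Both addback samples were nearer to CREB1 KO 1 than to CREB1 KO 2. For wild-type and S133A, the SD of log2 differences over abundant genes was 0.25 and 0.17 from CREB1 KO 1. From CREB1 KO 2 it was 0.53 and 0.50. Comparisons with the CREB1 knockout label therefore mix the difference between its samples with the added CREB. CREB1 itself stood at a log2 fold change of 2.19 (SE 0.43, unadjusted p = 0.000404) with wild-type CREB and 1.90 (SE 0.43, unadjusted p = 0.0012) with S133A. BMPR1B stood at -1.15 (SE 0.36) and -1.09 (SE 0.36), near each other for both forms. Replication-dependent histone genes had a median of -0.62 with wild-type CREB against the CREB1 knockout label and -0.60 against S133A (camera adjusted p = 6.07e-07 and 4.18e-11; adjusted p = 0.728 and 0.699 with an estimated correlation). Against the Cas9 sample their medians were 0.62 and -0.01 in the samples labelled CREB1 knockout, -0.36 with wild-type CREB and 0.25 with S133A. Against S133A, all 20 G1/S and all 22 G2/M genes were negative in the wild-type sample, with medians of -0.25 and -0.26 (adjusted p = 0.000128 and 0.000193; 0.699 for both with an estimated correlation). Cholesterol biosynthesis genes had medians of -0.08, 0.03 and -0.05 in wild-type and S133A against knockout and wild-type against S133A. edgeR called 0 genes in the 3 comparisons, with 368, 65 and 43 at an unadjusted p under 0.05, and DESeq2 and voom 0.

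With 0 genes called lower in the samples labelled CREB1 knockout, the planned follow-up of such genes in the addback samples had none to follow. Genes at an unadjusted p under 0.05 were followed in their place, a choice made after the data were seen. For 277 genes lower in both samples labelled CREB1 knockout (median -1.54), wild-type CREB exceeded S133A by a median log2 of 0.39, above all 10000 matched random lists (95% of them between 0.07 and 0.22). For 144 genes higher in both samples the median of wild-type minus S133A was -0.09, below all matched lists. For 225 genes lower in both samples labelled ATF1 knockout it was 0.24, at the 82.9th percentile. Each addback form rests on 1 sample. Across genes, with each gene's mean taken out, the wild-type sample had an r of 0.17 with Cas9 and S133A -0.14. Lists matched on expression do not remove such a difference, so the percentiles cannot tell it from a need for the serine that S133A lacks. Against Cas9, wild-type and S133A stood at -0.45 and -0.92 over the 277 genes and 1.10 and 1.22 over the 144. The same Cas9 sample was used to choose these genes.

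Genes of the CAMKK2 knockout were then compared with those of the CREB table, where other Cas9 samples serve as controls. The tables also differed in make-up. Mitochondrially encoded genes took 0.219% to 2.10% of counts in the CAMKK2 table and 6.12% to 10.6% in the CREB table. MALAT1 took 0.0163% to 0.0348% and 1.08% to 2.76%. Whether this lowered the overlap and correlations was not tested. No gene was called in both, since edgeR called 0 genes in the CREB table. At an unadjusted p under 0.05, 25 genes were lower both in CAMKK2 knockout and with the CREB1 label (5.65 by independent lists, Fisher's exact p = 8.7e-11) and 53 with the double knockout label (18.7, Fisher's exact p = 2.58e-12). For ATF1 the shared count was 11 (3.92, Fisher's exact p = 0.0014). Shared higher genes numbered 15, 4 and 33 for CREB1, ATF1 and the double knockout (6.2, 1.7 and 18.0 by independent lists; Fisher's exact p = 0.0012, 0.0864 and 0.000523). Fisher's test treats genes as independent, which co-regulated genes are not. The CREB1, ATF1 and double knockout lists share the same lone Cas9 sample, so their p-values are not separate evidence. Genes called in CAMKK2 knockout varied within labels of the CREB table (median absolute log2 difference 0.79, 95% of matched random lists 0.41 to 0.47). Such variable genes may enter both lists, and overlaps in opposite directions were not counted, so the excess cannot show a shared route. Across 14536 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.127, 0.0615 and 0.123, and Spearman's rho 0.0982, 0.0199 and 0.0738.

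Within the CREB table, log2 fold changes with the CREB1 and double knockout labels had a Pearson r of 0.759 across genes, those with CREB1 and ATF1 0.533, and those with ATF1 and double knockout 0.509. All share 1 Cas9 sample. In 10 simulations of unchanged groups every sample, Cas9 included, was redrawn from 1 common mean per gene, and r was 0.718, 0.71 and 0.705. The covariances minus the simulated ones were 0.04, -0.16 and -0.12. Genes at an unadjusted p under 0.05 in both and in the same direction numbered 220, 63 and 85, of which 87, 20 and 22 were higher. The simulations gave 256.8, 244.3 and 243 higher and 97.9, 112.4 and 109.2 lower, but from lists of other sizes. For CREB1, ATF1 and double knockout, the first simulation had 556, 564 and 563 genes higher and 469, 459 and 435 lower at that threshold. The data had 144, 44 and 350 higher and 277, 225 and 628 lower. The simulated spread thus differed from that of the data. The shared counts, r and covariances can therefore not be read against the simulated ones. No gene was called in both comparisons of a pair. The 2 samples labelled CREB1 knockout differed in their likeness to the double knockout. With each gene's mean over the CREB table taken out, CREB1 KO 1 had an r of 0.08 and 0.31 with the 2 double knockout samples. CREB1 KO 2 had -0.12 and -0.18, so the likeness of the 2 labels was not shared by both samples.

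The CREB inhibitor was set against vehicle after 72 h, 1 sample each, so the differences have no replicate check. The heat shock gene HSPA6 went from 13 counts to 2578, a ratio of 406 (95% exact counting interval 237 to 763), and the immediate early gene FOS, a textbook CREB target, from 8 counts to 1654 (ratio 423, 214 to 981). PIM1, a kinase gene, stood at 7.55 CPM with DMSO and 544 CPM with the inhibitor, the stress gene GADD45B at 5.16 and 350 CPM, and the clock gene PER1, another CREB target, at 14.8 and 859 CPM. RNU6-927P, a copy of the multi-copy U6 RNA whose reads may be shared, went from 1 count to 570 (ratio 1166, 208 to 46120). Among the lowest ratios, the olfactory receptor gene OR51E1 had 356 counts with DMSO and 0 with the inhibitor, at least 58-fold lower at a floor of 3 counts, and the phosphatase gene PTPRT 232 and 0, at least 37.8-fold lower. TTC34 had 774 counts and 1 (ratio 378, 67.7 to 14968), the claudin CLDN8 444 and 1 (217, 38.8 to 8595), NIPSNAP3B 418 and 3 (68.1, 23.2 to 332) and the transporter SLC45A2 603 and 4 (73.7, 28.6 to 271).

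Cholesterol biosynthesis genes had a median log2 ratio of 0.76 over 21 genes with the inhibitor, at the 99.2nd percentile of matched random lists. Of these genes 14 had positive and 7 negative ratios, and 95% of random lists lay between -0.17 and 0.67. Genes of a random list need not be regulated together, so lists of co-regulated genes reach an extreme percentile more easily. Percentiles here and below were not adjusted over the 27 lists. Scaled by library size alone the cholesterol median was 0.33, and the median of all genes -0.46, so the signs of small list medians depend on the scaling. FDFT1 stood at 238 CPM with DMSO and 2470 with it and the decarboxylase MVD at 21 and 154 CPM, while the reductase TM7SF2 (187 and 83.9 CPM) and HSD17B7 (71.1 and 34.3 CPM) were lower. INSIG1, which holds back sterol synthesis, stood at 538 and 2242 CPM, among the highest of the sterol sensing and uptake list (median 0.21, 34.6th percentile), and the exporter ABCA1 (10.2 and 1.66 CPM) was the lowest of the efflux list (-0.56, 2.75th). FASN stood at 786 and 6715 CPM in a fatty acid synthesis list with a median of 0.02 (13.6th).

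CREB target genes had a median of 1.55 over 16 genes with the inhibitor, above all 10000 matched lists, as did stress immediate early genes (2.04) and p53 targets (1.45), in which CDKN1A went from 16.8 to 640 CPM and BBC3 from 2.41 to 60.6 CPM. The unfolded protein and ATF4 list had a median of 1.10 (99.97th percentile), with DDIT4 at 37 and 840 CPM and CHAC1 at 14.2 and 266 CPM. It did not rise as a whole: 9 of its 24 genes had negative ratios, the lowest SDF2L1 (35.8 and 11 CPM) and CRELD2 (157 and 49.7 CPM). Ribosomal proteins had a median of 1.16 (99.5th), autophagy and lysosome genes 0.73 (99.8th) and G2/M genes 0.67 (99.4th). Mitochondrially encoded genes had a median of -1.01, below all matched lists, with MT-CO3 at 11304 and 3564 CPM. Of the 13 measured, 12 had negative ratios, but MT-ND4 (11467 and 12142 CPM) and MT-CO2 (7510 and 6555 CPM) moved little. Androgen receptor targets had -0.25 (1.38th percentile), with ACP3 at 182 and 7.04 CPM and C1orf116 at 120 and 3.25 CPM, while 15 of 33 had positive ratios, the highest ZBTB10 (53.5 and 284 CPM) and NDRG1 (60.8 and 144 CPM). Androgen receptor program regulators had -0.28 (1.6th), with FOXA1 at 377 and 86 CPM and GATA2 at 242 and 928 CPM. ATF1 stood at 24.3 and 58.8 CPM, CAMKK2 at 177 and 90.6 CPM, and CREB1 at 73.9 and 52.8 CPM. Medians for the other lists were -0.36 for G1/S genes (3.44th), 0.60 for nuclear oxidative phosphorylation (93.3th), 0.52 for calcium and AMPK kinases (96.6th), 0.33 for glycolysis and hypoxia (69.1th), 0.28 for luminal markers (32.6th), -0.09 for the CREB family (13.1th), -0.31 for histones (5.69th), 0.74 for structural small RNAs (74.8th) and 0.00 for interferon genes (48.1th). Few members were measured of the neuroendocrine (5, -0.23, 62.8th), mesenchymal (6, -0.20, 55.7th), basal (3, -1.04, 1.6th) and endothelial and blood (1, -2.11, 8.81th) lists.

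Over all 13506 genes, 1580 had a log2 ratio above 1 and 2449 below -1. Scaling by library size alone moved the median of all genes to -0.46 and these counts to 698 and 3954. The nuclear RNAs MALAT1 and NEAT1 took 3.72% (95% exact binomial interval 3.717 to 3.725) and 0.234% (0.233 to 0.236) of counts with DMSO and 8.84% (8.83 to 8.84) and 2.2% (2.199 to 2.208) with the inhibitor.

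**Figure D3:**
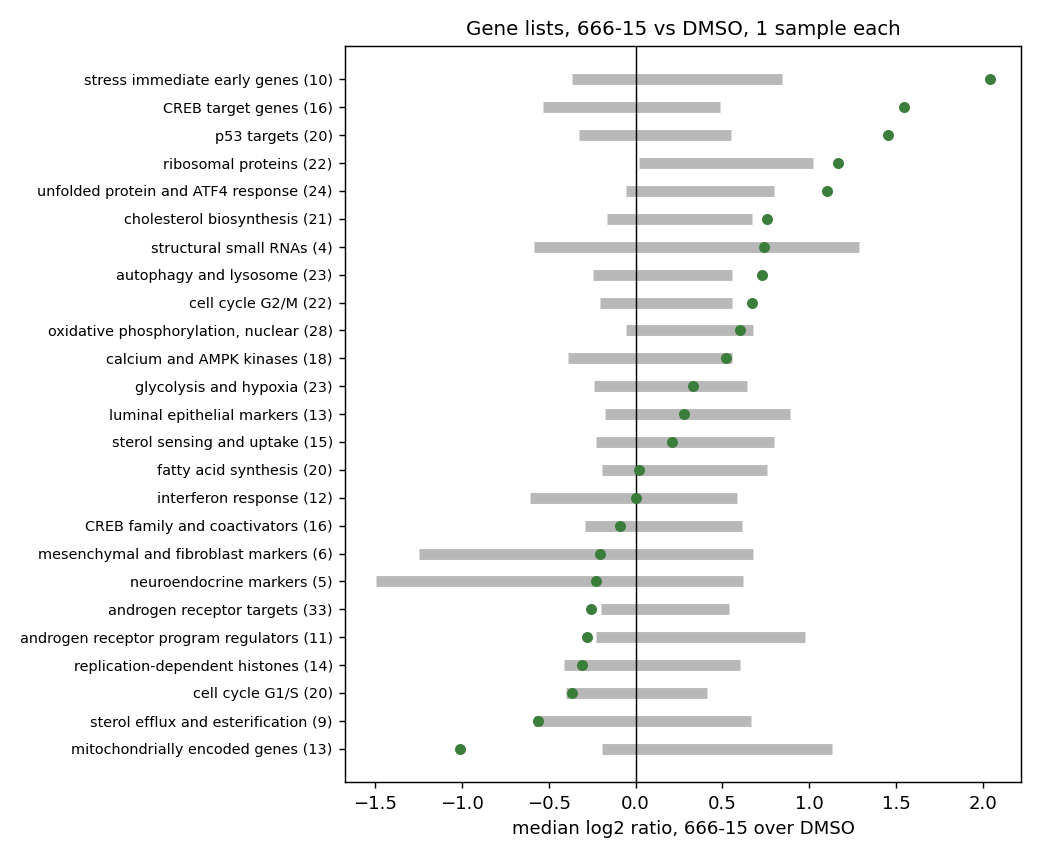
Median log2 ratio of each gene list with at least 4 measured genes, CREB inhibitor over DMSO (points, 1 sample each), with the middle 95% of 10000 expression-matched random lists (grey bars) and the number of genes in brackets. Stress immediate early genes (2.04), CREB targets (1.55) and p53 targets (1.45) lay above the bars, and mitochondrially encoded genes (-1.01) below.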

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

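The tests of GC content, depth, swapped labels and chromosome 2 were chosen after the results were seen. The test of whether the double knockout differs from the sum of the single ones picked out 3 gene lists by camera with the preset correlation: ribosomal proteins with a median log2 of -0.29 (22 of 22 negative, adjusted p = 0.0056), replication-dependent histones with -0.44 (14 of 15 negative, adjusted p = 0.0077) and luminal epithelial markers with -0.19 (11 of 14 negative, adjusted p = 0.0261). With an estimated correlation the adjusted p was 0.887 for each of the 3, and no gene was called in that contrast by edgeR, with 167 at an unadjusted p under 0.05, or by DESeq2 or voom. The lone Cas9 sample enters this contrast, so a list low in that sample alone comes out negative without any interaction. Ribosomal proteins had positive medians against it with all 3 labels, so their value cannot show that the double knockout differs from the sum.

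The CAMKK2 knockout changes were weighed against chance and against differences between C4-2 lines that arise whatever gene is targeted. The 6 samples can be split into 3 and 3 in only 10 ways, which cannot give a share under 0.05: 1 split, the real one, reached 361 genes, and the highest of the others called 0. Of the called genes 359 were measured in the CREB table, where they differed between samples with the same knockout label by a median absolute log2 of 0.79, at the 100th percentile of matched random lists (95% between 0.41 and 0.47). The called genes were thus more variable between samples in which CAMKK2 was not targeted, and a part of the 361 may come from line-to-line variation, such as between clones. The labels do not say whether the 3 knockout samples came from 1 clone. Over abundant genes the SD of log2 differences was 0.13 between CAMKK2 KO 1 and 2 and 0.14 between Cas9 1 and 3. Pairs of a group with Cas9 2 or CAMKK2 KO 3 had 0.51 to 0.60, and samples of 1 CREB-table label 0.41 to 0.58. All 3 knockout samples had the same shift of chromosome 2 (0.37, 0.37 and 0.36). The closest pairs may thus be repeats of 1 line. An effect of CAMKK2 itself and of 1 knockout line cannot be separated here, and both stay open.

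Cas9 2 and CAMKK2 KO 3 stood apart from the other 4 samples of the CAMKK2 table. Across genes, the log2 ratio of these 2 to the other 4 within each group rose with GC share (Spearman's rho 0.726, medians -0.52 in the lowest and 0.51 in the highest 0.25 of genes by GC share), so a difference in GC bias between library preparations is a candidate explanation. Unequal depth is argued against, since thinning all 6 to the smallest total left 0.902 of the share of variance on the separating component. Swapped labels are argued against too, because CAMKK2 KO 3 had 0.112 of the CAMKK2 CPM of Cas9 2. Mitochondrially encoded genes took 0.219% to 0.309% of counts in these 2 samples and 1.34% to 2.10% in the other 4, and no biological explanation was tested.

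Whole chromosomes shifted in both tables. In CAMKK2 knockout cells the median log2 fold change of chromosome 2 was 0.353, all 17 of its windows of 50 neighbouring genes lay above the median of all genes, and taking out the trend on GC share and length left 1.03 of that value. As the block already balances GC share, that ratio says little, so each sample was set against the mean of the Cas9 samples, a check added after the data were seen. There the trend moved chromosome 22 in CAMKK2 KO 3 from 0.31 to 0.10, while chromosome 2 went from 0.41, 0.42 and 0.23 to 0.37, 0.37 and 0.36 in the 3 knockout samples, which argues against GC bias. In the CREB table, where the test was set before the chromosome medians were computed, the furthest was chromosome 13 in double KO 1 at -0.473 with the trend taken out, with all 4 windows on that side. A difference in chromosome copy number between the lines is a candidate explanation for both, though DNA was not analysed here. A shift of 0.353 is too small to make up the whole of the changes of TRIB2 (4.07, SE 0.07), LPIN1 (1.06, SE 0.06) or IFIH1 (1.11, SE 0.11) in the blocked fit.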

How the results depend on the processing

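The direction of the 20 named genes called in CAMKK2 knockout without the block never turned. The other named genes were not followed in this way. Counts of calls moved, and the cause was not tested. Against 361 called genes, other settings called 339 to 403 (library size, RLE, voom or no filter), 221 with at least 50 counts, 999 with DESeq2, 57 at an adjusted p under 0.01 and 24 to 282 when 1 sample was left out (52 without Cas9 1, 203 without Cas9 2, 24 without Cas9 3, 54 without CAMKK2 KO 1, 42 without CAMKK2 KO 2). The cholesterol biosynthesis median of 0.05 was 0.01 (0.0090) by library size and -0.06 to 0.12 with 1 sample left out: 0.12 without Cas9 1, -0.016 without CAMKK2 KO 2 and -0.057 without CAMKK2 KO 3. Setting Cas9 2 and CAMKK2 KO 3 apart, a choice made after the data were seen, gave 4762 genes, and the other 4 samples alone 3077. With sample numbers as a block the count was 8 and 14 of 20 named genes lost their call, and samples did not correlate with their own number throughout (r 0.63, -0.71 and -0.69), so the numbers were not taken as pairs. With an estimated correlation 0 lists passed camera.

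In the CREB table edgeR's 0 calls held with voom. In the order CREB1, ATF1 and double knockout against Cas9, double against CREB1, double against ATF1 and CREB1 against ATF1 knockout, DESeq2 called 3, 6, 30, 1, 104 and 45 genes and edgeR without a filter 45, 20, 142, 73, 383 and 238. Without a filter it called 7 for each addback form against CREB1 knockout, 0 between them, and 25 for the double knockout against the sum of the single ones. Library size called 1 gene for ATF1 knockout against Cas9 and 1 for double against ATF1 knockout. Technical columns taken as samples, which is not a valid test of replicates, gave 3243, 2012 and 5479 genes against Cas9. Pairing the 4 samples compared by crossed numbers (r 0.11 and 0.14, where same numbers had -0.11 and -0.14) gave 9 genes for double against CREB1 knockout and 17 for CREB1 against ATF1 knockout.

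Leaving out 1 sample of the CREB table gave 0 to 1 calls for CREB1 knockout (1 without CREB1 KO 1), 0 to 3 for ATF1 knockout (3 without ATF1 KO 2) and 1 to 2 for the double knockout (1 without double KO 1, 2 without double KO 2). It gave 0 to 4 for double against CREB1 knockout (1 without CREB1 KO 1, 1 without double KO 1, 4 without double KO 2), 1 to 77 for double against ATF1 knockout (1 without ATF1 KO 1, 77 without ATF1 KO 2, 3 without double KO 1, 6 without double KO 2), 0 to 52 for CREB1 against ATF1 knockout (1 without CREB1 KO 1, 1 without ATF1 KO 1, 52 without ATF1 KO 2) and 1 for S133A against CREB1 knockout without CREB1 KO 1. The cholesterol median ran from -0.060 to 0.34 for CREB1 knockout (0.34 without CREB1 KO 2), -0.27 to 0.22 for ATF1 knockout (-0.27 without ATF1 KO 1) and -0.051 to 0.54 for the double knockout (0.54 without double KO 2). It ran from -0.19 to 0.36 for double against CREB1 knockout (0.36 without CREB1 KO 1, 0.33 without double KO 2), -0.11 to 0.45 for double against ATF1 knockout (0.38 without ATF1 KO 1, 0.45 without double KO 2) and -0.097 to 0.33 for CREB1 against ATF1 knockout (0.33 without CREB1 KO 2, 0.32 without ATF1 KO 1). For wild-type addback against CREB1 knockout it ran from -0.22 (without CREB1 KO 2) to 0.056, and for S133A from -0.11 (without CREB1 KO 2) to 0.17 (without CREB1 KO 1). The lone Cas9 and addback samples could not be left out. With an estimated correlation, or by fry, 0 lists passed in each comparison in which camera with the preset correlation passed any (8, 9, 7, 5, 7, 5, 6 and 3 lists).

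For the inhibitor, 3370 genes had a log2 ratio above 1 and 7338 below -1 with no floor on counts, 698 and 3954 by library size, where the cholesterol median fell from 0.76 to 0.33. Shared genes with the CAMKK2 knockout went from 0 among called genes to 15 higher and 25 lower (CREB1), 4 and 11 (ATF1) and 33 and 53 (double) at an unadjusted p under 0.05, and those within the CREB table to 63, 220 and 85. The genes followed in the addback samples went from 0 to 277. Settings for normalized values did not apply to counts.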

Other observations

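Chromosome medians showed which samples of the CREB table resembled each other, a pattern seen in the data and described as values. With the trend on GC share and length taken out, chromosome 22 stood at -0.25 in CREB1 KO 1, -0.30 and -0.28 in the 2 samples labelled double knockout, and -0.31 in each addback sample, but at 0.05 in CREB1 KO 2 and 0.02 and 0.06 in the samples labelled ATF1 knockout. Chromosome 13 stood at -0.41 in CREB1 KO 1, -0.47 and -0.31 in the double knockout samples, and -0.45 and -0.44 with wild-type CREB and S133A, against -0.07 in CREB1 KO 2 and -0.06 and -0.10 in the ATF1 samples. Chromosome 8 stood at -0.29 in ATF1 KO 1, chromosomes 7 and 18 at -0.25 and 0.33 in ATF1 KO 2, and chromosome 16 at 0.20 in ATF1 KO 1 and 0.24 in double KO 1. CREB1 itself lies on chromosome 2, whose median was 0.35 in CAMKK2 knockout cells, where CREB1 stood at 0.16 (SE 0.28).

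The CAMKK2 table differed in make-up from the other 2 tables, although the labels give 1 protocol for all samples. MALAT1 took 0.0163% to 0.0348% of counts in the CAMKK2 table, 1.08% to 2.76% in the CREB table and 3.72% to 8.84% in the treatment table. The signal recognition particle RNAs of the RN7SL genes took 0.0022% to 0.0078%, 1.29% to 3.64% and 2.43% to 3.65%. The mitochondrial ribosomal RNA MT-RNR2 went the other way, with 0.131% to 0.701% of counts in the CAMKK2 table and at most 0.000738% in the others.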
